A study of Mus musculus and Homo sapiens with 18 samples.

How the data were processed

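Gene expression was measured by RNA sequencing in primary mouse mammary epithelial cells (MMECs) and in MCF7, an established human breast cancer cell line that expresses the estrogen receptor ERα. Per the labels' protocols, RNA was extracted with the AllPrep kit, RNA with a RIN over 8 was taken forward, and libraries were made with the TruSeq RNA kit. TopHat, HTSeq and the genome builds GRCh38 and GRCm38 are named per the submitters' processing notes, with no version of either tool. The annotation, the use of strand in counting and the scaling method are not given in the sources used here. The deposited values are log2 normalised counts per gene, in 1 table of 16 mouse libraries and 1 table of 2 MCF7 libraries, per the file headers. The 2 tables were normalised separately, and no test was made across them.

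After back-transformation, 2^x minus 1, every value was a whole multiple of 1 step per library, with a tolerance of 0.1 of a step, checked up to 200 steps. The step was taken as 1 read, which gave the recovered reads per library. The deposited pseudocount was therefore 1, and fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. Of the 24020 named genes in the mouse table, 22476 symbols were found in GENCODE release M21 on GRCm38, which gave the locations and the GC content of transcripts. 1 row had no gene name, held at most 1.38e-05% of a library's reads, and was left out of the totals and the tests. Counting that ignores strand cannot separate a gene from an overlapping or antisense neighbour, and reads of near-identical copies may be shared. How far this affects the pseudogene Rps13-ps1 was not tested. Nor was it tested for related genes such as Oas2 and Oas3, Gbp2 and Gbp3, Ifit1 and Ifit2, and C1qb and C1qc, although the members of each pair do not overlap in position.

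Groups and replicate numbers came from the sample titles. 1 conflict over estradiol or DMSO was found: WP_E2 replicate 1 is titled as estradiol-treated and its treatment label names DMSO. It was kept in the group of its title, with the other reading as an alternative. The treatment label of WT_DMSO replicate 2 leaves out the Cre adenovirus that the labels of the other MMEC libraries name. The titles differ from these labels: all WP, WP;HA-hERa and WP;HA-mERa titles name AdCre and no WT title does. Whether WT cells received the virus is therefore uncertain. Nothing in the labels says whether replicates were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Libraries of the same group differed by more than counting noise, with a chi-square per gene of 1.95 to 63.2 in MMECs and 1.95 in MCF7, and none was treated as a duplicate. Their log2 values had a Pearson correlation across genes of 0.993 to 0.997 in MMECs and 0.992 in MCF7, and genes are not independent replicates.

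Genes with a mean of at least 10 normalised counts over the 16 mouse libraries were tested, 14116 in all. A linear model with 1 mean per group of genotype and treatment was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. All 8 groups shared 1 estimate of the spread, with 8 residual and 5.57 prior degrees of freedom. The 12 comparisons were the estradiol effect in each of the 4 genotypes, its mean over both transgenic genotypes and over WT and WP, 2 differences between estradiol effects, and 4 comparisons of genotypes averaged over both treatments. All tests were two-sided and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called at an adjusted p under 0.05. Errors of single genes' fold changes are standard errors of the model, and errors of levels are standard deviations. Errors of list medians come from 1000 bootstrap draws of the list's genes, so they measure the spread over genes, which are not independent, and not over libraries.

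The 18 gene lists were fixed before the data were examined, as were the comparisons, the tests, the first set of other settings and the rule for named genes. They held 498 symbols, of which 493 were in the mouse table, 5 of them under an older symbol, and 460 were tested. The tested members numbered 35 for interferon-stimulated genes, 48 for mitosis and S phase, 56 for p53 target genes, 27 for NF-kB and inflammatory cytokines, 27 for immediate early genes, 23 for the unfolded protein response, 24 for cholesterol synthesis and 27 for hypoxia and glycolysis. The cell type lists had 18 tested luminal keratins and junction genes, 16 markers of hormone-sensing luminal cells, 15 of luminal progenitor and alveolar cells, 27 of basal and myoepithelial cells, 23 of fibroblasts, 14 of endothelial cells, 15 of immune cells and 6 of adipocytes. The estrogen lists had 58 genes induced in MCF7 cells and 31 genes that respond in mouse mammary gland and uterus, 13 and 20 of which stood also in other lists. Each list was compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, and the 216 tests were adjusted together. The same test with an estimated correlation and fry, which tests a list by itself for a change that goes on balance 1 way, were alternatives. Named genes were Esr1, Trp53, Pgr, Greb1 and Areg in every comparison, the 8 called genes with the largest change in each direction whose groups did not overlap in any library, and up to 4 called members per list with the smallest adjusted p. In a comparison without a call, the 3 genes with the smallest p in each direction were named. Predicted gene models, mitochondrial and ribosomal protein genes were left out of the choice by size.

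That first set held no filter, a minimum of 100, a pseudocount of 8, quantile normalization, limma-voom on the recovered reads, no mean-variance trend, only the groups compared, the replicate number as a block, the replicate number as a block within genotype, each library left out in turn, E2 or DMSO libraries only, and the other reading of WP_E2 replicate 1. A correction for the GC content of transcripts, alone and with the replicate block, the removal of 3 libraries that stood apart, and the gene list tests without each library were added after seeing the data. The procedure was tested on simulated counts for 14116 genes, with 200 genes changed and 10 simulations per comparison. It recovered 67.2% of changes of 0.5 on the log2 scale and 85.1% of changes of 1 for estradiol in WT, 67.3% and 86.4% in WP, 67.6% and 85.2% in WP;HA-hERa, and 67.3% and 86.7% in WP;HA-mERa. The figures were 78.8% and 92.8% for the mean of both transgenes, 78.8% and 92.7% for the mean of WT and WP, 68.4% and 86.7% for the difference between those means, and 48.1% and 78.5% for the difference between the transgenes. For the genotypes they were 81.3% and 91.3% for WP against WT, 78.8% and 92.7% for WP;HA-hERa against WP, 77.5% and 93.7% for WP;HA-mERa against WP, and 78.5% and 91.3% between the transgenic genotypes. False calls made up 4.31% to 6.51% of all calls. The simulated changes had sizes of 0.5, 1 or 2, and counts were drawn independently for each gene. With fewer changed genes the adjusted p-values are stricter, and fewer changes would be recovered. These figures therefore do not show how many changes were missed in comparisons where no gene was called. Plots were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.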

Results

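RNA was sequenced from primary mouse mammary epithelial cells (MMECs) of 4 genotypes and from MCF7 human breast cancer cells. The MMECs were wild type (WT), carried floxed alleles of the tumor suppressor gene p53 with the allele that the labels call WcrH (WP), or carried in addition a transgene for human or mouse ERα with an HA tag (WP;HA-hERa and WP;HA-mERa). Per the treatment labels, cells had received a Cre adenovirus, but the label of WT_DMSO replicate 2 does not name it. The titles of the other genotypes name it as AdCre, and no WT title does. Cells were kept without hormone for 72 h, and then received estradiol (E2) or its vehicle DMSO for 6 h. Each of the 8 groups of genotype and treatment had 2 libraries, named below by group and replicate (hERa and mERa stand for the transgenic genotypes), and MCF7 cells in full medium had 2. The mouse libraries held 24236944 (WP_DMSO replicate 2) to 34180728 (mERa_E2 replicate 1) recovered reads, with 18470 to 19086 genes above 0 reads, and the MCF7 libraries held 12792669 and 11462626. The first principal component of the mouse libraries carried 50.8% of the variance, the second 16.9% and the third 9.84%. Replicate 1 of WP_E2, of hERa_E2 and of WP_DMSO stood apart from its partner in AT-rich transcripts such as Mki67, a proliferation marker, with log2 levels of 10.81, 10.78 and 11.42 against 11.95, 12.23 and 12.14. By the chi-square per gene, WP_E2 replicate 2 was furthest from the other WP libraries, at 63.2, 60.7 and 54.3, where those lay at 5.96 to 18.3 of each other.

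The targeted genes followed the genotype labels in every library as far as their reads can show it. Trp53 (chromosome 11, 69580359 to 69591873, GRCm38), the gene of p53, had a log2 level of 11.96 ± 0.06 (SD, n = 4) in WT, 10.36 ± 0.16 in WP, 9.50 ± 0.11 in WP;HA-hERa and 10.23 ± 0.10 in WP;HA-mERa. The single libraries ranged from 11.87 to 12.02 in WT and from 9.39 to 10.55 in the other genotypes. Reads of exons outside a deleted part still count for Trp53, and the labels do not say which exons are floxed. Esr1 (chromosome 10, 4611593 to 5005614), the gene of ERα, had a level of 7.99 ± 0.08 in WT, 7.52 ± 0.07 in WP, 7.13 ± 0.09 in WP;HA-hERa and 9.43 ± 0.07 in WP;HA-mERa. All 4 libraries with the mouse transgene lay between 9.36 and 9.50, and the other 12 lay between 7.06 and 8.07. Reads of the human transgene reach the mouse Esr1 row only where they align to the mouse genome, so Esr1 checks the mouse transgene and not the human one. The library titled WP_E2 replicate 1, whose treatment label names DMSO, had Pgr at 6.86 and Greb1 at 7.09, next to 7.10 and 7.25 in its partner and 5.05 and 5.42 for Pgr and 4.13 and 4.96 for Greb1 in the WP_DMSO libraries. Both genes rose with estradiol in WT too, so these levels argue against the DMSO reading of that library. Counts given below for the DMSO reading rest on the treatment label alone.

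**Figure D1:**
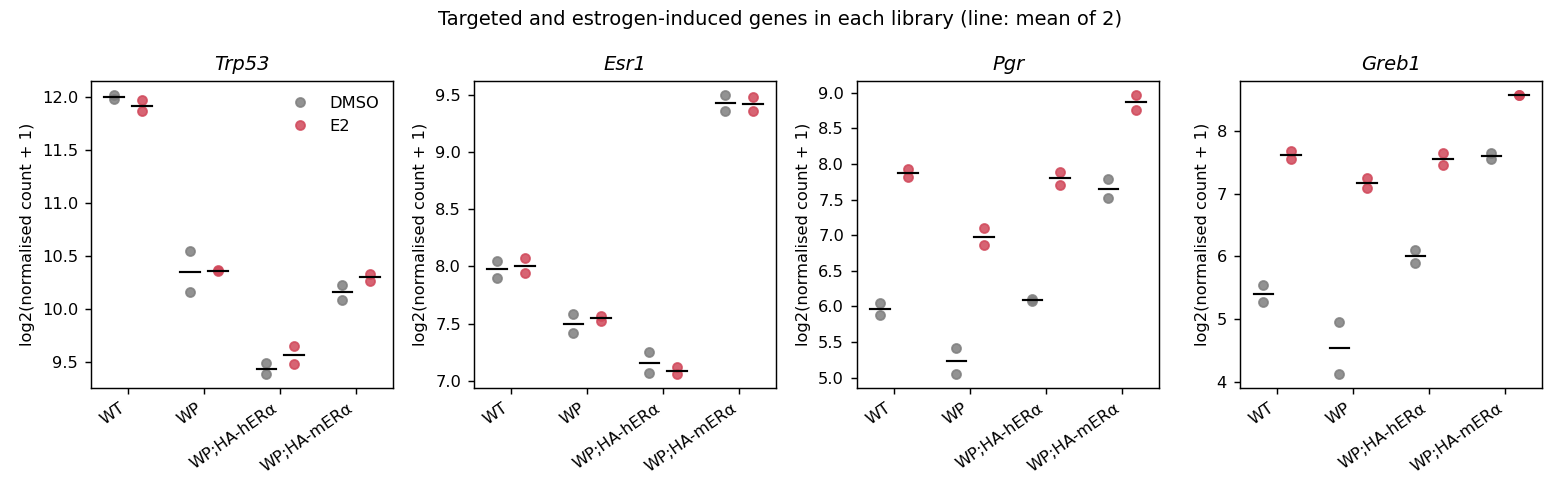
Level of Trp53, Esr1, Pgr and Greb1 in each mouse library, as log2(normalised count + 1), by genotype, with a point per library and a line at the mean of 2. Esr1 lay between 9.36 and 9.50 in the 4 WP;HA-mERa libraries and Trp53 was highest in the 4 WT libraries, while Pgr and Greb1 were higher with E2 in each genotype.

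The first question was what 6 h of estradiol changed in WT cells. Estradiol raised Greb1 (chromosome 12, 16670615 to 16800886), an estrogen-induced cofactor of ERα, by 2.21 ± 0.20 on the log2 scale (SE, n = 2 against 2, adjusted p = 0.00016) and Pgr (chromosome 9, 8899833 to 8968611), the progesterone receptor gene, by 1.92 ± 0.15 (adjusted p = 3.1e-05). Ptpn5, a tyrosine phosphatase, rose by 1.87 ± 0.20, Tmem86a by 1.34 ± 0.06 and Ngfr, the low-affinity neurotrophin receptor, by 1.28 ± 0.14, while the immediate early gene Ier2 fell by 0.81 on the log2 scale (SE 0.09, adjusted p = 0.0009). Areg (chromosome 5, 91139599 to 91148432), the gene of the EGF receptor ligand amphiregulin, did not pass at -0.32 ± 0.13 (adjusted p = 0.47). Of 35 interferon-stimulated genes, 5 were higher, 0 lower and 30 not passed, and 30 were higher when adjusted over the list alone. Trim30a (0.40 ± 0.06) and Usp18 (0.40 ± 0.05) were among them. The list's median was 0.26 (camera adjusted p = 4.4e-33, and adjusted p = 0.056 with an estimated correlation). WT_DMSO replicate 2, whose label does not name the adenovirus, was one of the control libraries, and both controls had lower list medians, 9.40 and 9.35, than the E2 libraries, 9.72 and 9.64. Among 27 immediate early genes 2 were lower, Ier2 and Dusp6, 0 higher and 25 not passed, with 14 lower when adjusted over the list alone and a median of -0.22 (camera adjusted p = 4.3e-17, and adjusted p = 0.075 with an estimated correlation). The estrogen lists were not called: 2 of 58 genes induced in MCF7 cells (adjusted p = 0.40) and 2 of 31 genes of mouse tissues (adjusted p = 0.48) were higher, in both cases Pgr and Greb1, with 0 lower. When adjusted over the list alone, 2 were higher in each list and 1 and 3 lower. Both lists had a negative median (-0.03), a positive mean (0.02) and a test direction of lower. Luminal keratins and junction genes, with 0 of 18 passed and 3 lower when adjusted over the list alone, were called lower (median -0.012, camera adjusted p = 0.029, and adjusted p = 0.51 with an estimated correlation).

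The limma test called 45 of 14116 genes in WT, 38 higher and 7 lower. Without WT_E2 replicate 1 it called 15 and without WT_E2 replicate 2 it called 18. The count was 69 with only the WT libraries in the fit and 147 without the 3 libraries that stand apart in AT-rich transcripts. Of the genes named above, Trim30a was lost without WT_E2 replicate 1 (adjusted p = 0.087), Usp18 without either WT_E2 replicate 1 or 2 (0.0599 and 0.0611), and Dusp6 without WT_E2 replicate 1 (0.149), WT_E2 replicate 2 (0.441) or WT_DMSO replicate 1 (0.224). The call of the luminal keratins was lost without WT_E2 replicate 1 (median -0.0033, adjusted p = 0.360), without WT_DMSO replicate 2 (-0.037, adjusted p = 0.143) and with GC correction (adjusted p = 0.478). Their median was -0.047 without WT_E2 replicate 2 and -0.057 without WT_DMSO replicate 1.

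In WP cells, which have less Trp53, estradiol raised Greb1 and Pgr as well. Greb1 rose by 2.62 ± 0.20 (n = 2 against 2, adjusted p = 3.9e-05), Ptpn5 by 1.92 ± 0.20 (adjusted p = 0.00056), Pgr by 1.74 ± 0.15 (adjusted p = 6.1e-05) and Tmem86a by 0.91 ± 0.06 (adjusted p = 1.1e-05). Tmod1, which caps actin filaments, rose by 1.98 ± 0.27 (adjusted p = 0.0063), a call that was lost without WP_DMSO replicate 2 (adjusted p = 0.079). Areg did not pass at -0.20 ± 0.13 (adjusted p = 0.57). None of 27 immediate early genes passed, 8 were lower when adjusted over the list alone, and the median was -0.14 (camera adjusted p = 6.0e-08, and adjusted p = 0.18 with an estimated correlation). Of 35 interferon-stimulated genes 0 passed, 2 were higher when adjusted over the list alone, and the median was 0.046 (camera adjusted p = 0.013, and adjusted p = 0.52 with an estimated correlation). That call was lost without WP_DMSO replicate 2 (median -0.010, adjusted p = 0.563), and the median was 0.091 without WP_DMSO replicate 1 and 0.082 without WP_E2 replicate 2. The estrogen lists again held 2 higher genes each, Pgr and Greb1, and were not called (adjusted p = 0.85 and 0.90), with medians of -0.01 each, means of 0.04 and 0.06, and a test direction of higher. Of 15 immune cell markers 0 passed, 4 were lower when adjusted over the list alone, and the median was -0.23 (camera adjusted p = 0.0031, and adjusted p = 0.31 with an estimated correlation), a call that was lost without WP_E2 replicate 2 (adjusted p = 0.0511). Without WP_DMSO replicate 1 the median of the immediate early genes was -0.094. By limma, 21 genes were higher and 0 lower, with 1636 genes at an unadjusted p under 0.05 and 23 calls by limma-voom. The count was 117 without WP_E2 replicate 2 and 10 without WP_DMSO replicate 1. It was 0 with only the WP libraries in the fit, and 8 with WP_E2 replicate 1 counted as DMSO, as its treatment label has it.

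In WP;HA-hERa cells estradiol raised Tmod1 by 2.38 ± 0.27 (n = 2 against 2, adjusted p = 0.0013), Pgr by 1.72 ± 0.15 (adjusted p = 6.1e-05), Ngfr by 1.30 ± 0.14 (adjusted p = 0.0009) and Tmem86a by 1.05 ± 0.06 (adjusted p = 1.9e-06). Greb1 rose by 1.55 ± 0.20 (adjusted p = 0.0032), a call lost without hERa_E2 replicate 2 (adjusted p = 0.0531), and Areg did not pass at -0.41 ± 0.13 (adjusted p = 0.39). Inflammatory cytokine genes were among those that fell. Of 27 NF-kB and cytokine genes 5 were lower, 0 higher and 22 not passed, and 8 were lower when adjusted over the list alone (median -0.07, camera adjusted p = 0.00013, and adjusted p = 0.074 with an estimated correlation). Among them were Il6, the gene of interleukin 6, at -0.67 ± 0.10 (adjusted p = 0.0081) and the chemokine gene Cxcl1 at -0.55 ± 0.08 (adjusted p = 0.0093). The Il6 call was lost without hERa_E2 replicate 2 (adjusted p = 0.0929), hERa_DMSO replicate 1 (0.0783) or hERa_DMSO replicate 2 (0.0936), and the Cxcl1 call without hERa_E2 replicate 2 (0.127) or hERa_DMSO replicate 2 (0.235). Of 27 basal and myoepithelial markers 0 passed, 4 were higher when adjusted over the list alone, and the median was 0.12 (camera adjusted p = 1.8e-05, and adjusted p = 0.17 with an estimated correlation), or 0.073 without hERa_DMSO replicate 2. Of 27 immediate early genes 1 was lower, with 8 lower when adjusted over the list alone (median -0.13, camera adjusted p = 1.2e-10, and adjusted p = 0.13 with an estimated correlation). The estrogen lists were not called, with 2 higher and 0 lower of 58 MCF7 genes (adjusted p = 0.90) and 2 higher and 0 lower of 31 mouse genes (adjusted p = 0.89). When adjusted over the list alone, 3 were higher and 0 lower, and 5 higher and 6 lower. Their medians, -0.00035 and -0.0015, were negative and their means, 0.02 and 0.03, positive, with a test direction of higher. By limma, 40 genes were higher and 12 lower. The count of 52 fell to 26 without hERa_E2 replicate 1, 13 without hERa_E2 replicate 2, 29 without hERa_DMSO replicate 1 and 10 without hERa_DMSO replicate 2. It was 33 with no filter, 26 with no mean-variance trend and 19 with only the WP;HA-hERa libraries in the fit.

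Further lists were called with estradiol in WP;HA-hERa, cell type markers among them. Of 23 fibroblast markers 0 passed, 7 were higher and 1 lower when adjusted over the list alone, and the median was 0.10 (camera adjusted p = 0.0039, and adjusted p = 0.40 with an estimated correlation). That call was lost without hERa_E2 replicate 2 (adjusted p = 0.326), and the median was 0.066 without hERa_DMSO replicate 2. Of 35 interferon-stimulated genes 0 passed, 1 was higher when adjusted over the list alone, and the median was -0.053 (camera adjusted p = 0.017, and adjusted p = 0.54 with an estimated correlation), a call lost without hERa_E2 replicate 2 (adjusted p = 0.148). None of 48 genes of mitosis and S phase passed, also when adjusted over the list alone, and the median was -0.062 (camera adjusted p = 4.8e-05, and adjusted p = 0.52 with an estimated correlation). It was -0.094 without hERa_E2 replicate 1 and -0.030 without hERa_E2 replicate 2. None of 27 hypoxia and glycolysis genes passed, 1 was higher when adjusted over the list alone, and the median was 0.093 (camera adjusted p = 3.0e-05, and adjusted p = 0.42 with an estimated correlation).

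In WP;HA-mERa cells the response to estradiol started from higher levels. Tmem86a rose by 0.87 ± 0.06 (n = 2 against 2, adjusted p = 2.1e-05), Pgr by 1.21 ± 0.15 (adjusted p = 0.0039) and Ngfr by 1.15 ± 0.14 (adjusted p = 0.0042), and Greb1 did not pass at 0.97 ± 0.20 (adjusted p = 0.068). Areg did not pass at 0.09 ± 0.13 (adjusted p = 0.89). The gene list of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, had 1 higher gene, 0 lower and 22 not passed of 23, with 17 higher when adjusted over the list alone and a median of 0.28 (camera adjusted p = 8.9e-19, and adjusted p = 0.17 with an estimated correlation). Replicate 2 of mERa_E2 carried most of this shift: without it the median was 0.086, and without mERa_E2 replicate 1 it was 0.52. The gene that passed was Ppp1r15a, a subunit of the phosphatase that restarts translation, at 0.53 ± 0.10 (adjusted p = 0.049). Of 27 immediate early genes 1 was lower and 26 not passed, with 2 higher and 11 lower when adjusted over the list alone (median -0.16, camera adjusted p = 0.00019, and adjusted p = 0.39 with an estimated correlation), and the median was -0.10 without mERa_DMSO replicate 2. The MCF7 estrogen list had 1 higher and 0 lower gene of 58, with 5 higher when adjusted over the list alone (median 0.02, camera adjusted p = 0.027, and adjusted p = 0.32 with an estimated correlation). Its call was lost without mERa_DMSO replicate 1 (adjusted p = 0.316) or mERa_E2 replicate 1 (0.117) and with GC correction (0.0621), and its median was 0.0078 without mERa_E2 replicate 1, 0.043 without mERa_E2 replicate 2 and 0.033 without mERa_DMSO replicate 2. The mouse list, with 1 higher and 0 lower of 31 and 4 higher and 4 lower when adjusted over the list alone, was not called (adjusted p = 0.52). The calls of Pgr, Ngfr and Ppp1r15a were lost without mERa_E2 replicate 2 (adjusted p = 0.108, 0.0677 and 0.540). Without mERa_DMSO replicate 1 those of Pgr and Ppp1r15a were lost (0.10 and 0.509), and without mERa_DMSO replicate 2 those of Ngfr and Ppp1r15a (both 0.0699). By limma, 31 genes were higher and 15 lower. The count of 46 became 175 without mERa_E2 replicate 1, 2 without mERa_E2 replicate 2, 3 without mERa_DMSO replicate 1 and 6 without mERa_DMSO replicate 2. It was 14 with no filter, 10 with no mean-variance trend and 139 without the 3 libraries that stand apart.

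Further lists were called with estradiol in WP;HA-mERa, again with cell type markers. Of 23 fibroblast markers 0 passed, 2 were lower when adjusted over the list alone, and the median was -0.066 (camera adjusted p = 0.0041, and adjusted p = 0.40 with an estimated correlation). Of 14 endothelial markers 1 was higher, also when adjusted over the list alone, and the median was 0.16 (camera adjusted p = 0.020, and adjusted p = 0.39 with an estimated correlation), a call lost without mERa_E2 replicate 1 (adjusted p = 0.0660) or mERa_DMSO replicate 1 (0.0809). None of 48 genes of mitosis and S phase passed, also when adjusted over the list alone, and the median was -0.10 (camera adjusted p = 4.7e-05, and adjusted p = 0.52 with an estimated correlation). Of 24 cholesterol synthesis genes 1 was lower, 4 were lower when adjusted over the list alone, and the median was -0.092 (camera adjusted p = 1.1e-07, and adjusted p = 0.39 with an estimated correlation). Of 35 interferon-stimulated genes 0 passed, 1 was lower when adjusted over the list alone, and the median was -0.075 (camera adjusted p = 0.0042, and adjusted p = 0.49 with an estimated correlation). Without mERa_E2 replicate 2 the calls were lost for fibroblast markers (adjusted p = 0.132), mitosis (median -0.025, adjusted p = 0.371), cholesterol synthesis (-0.038, adjusted p = 0.109) and interferon-stimulated genes (-0.017, adjusted p = 0.608). Without mERa_E2 replicate 1 the medians were -0.11 for fibroblast markers, -0.17 for mitosis and -0.18 for cholesterol synthesis, and without mERa_DMSO replicate 1 that of mitosis was -0.068.

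Averaged over WT and WP, estradiol raised Greb1 by 2.42 ± 0.14 (n = 4 against 4, adjusted p = 6.5e-07), Ptpn5 by 1.90 ± 0.14, Pgr by 1.83 ± 0.10 (adjusted p = 6.5e-07), Tmod1 by 1.69 ± 0.19 and Tmem86a by 1.13 ± 0.04 (adjusted p = 7.6e-09). The transcription factor gene Fos (-0.76 ± 0.11, adjusted p = 0.0047), Ier2 (-0.63 ± 0.06, adjusted p = 0.00014) and Cxcl1 (-0.42 ± 0.06, adjusted p = 0.0028) fell. Of 27 immediate early genes 6 were lower, 0 higher and 21 not passed, with 16 lower when adjusted over the list alone (median -0.16, camera adjusted p = 2.8e-16, and adjusted p = 0.080 with an estimated correlation). Interferon-stimulated genes had 5 higher and 0 lower of 35, with 22 higher when adjusted over the list alone (median 0.14, camera adjusted p = 1.1e-19, and adjusted p = 0.062 with an estimated correlation), among them Trim30a (0.30 ± 0.04) and Stat2 (0.24 ± 0.03). WT carried this mean, with a median of 0.26 against 0.046 in WP, and 1 of its controls is the library whose label does not name the adenovirus. Its list median was 9.35, beside 9.40 in the WT control whose label names the virus. The MCF7 list had 2 higher and 1 lower gene of 58 and the mouse list 2 higher and 2 lower of 31, neither called (adjusted p = 0.63 and 0.64). When adjusted over the list alone, 2 genes were higher in each, and 1 and 3 lower. Their medians were -0.04 and -0.05, their means 0.03 and 0.04, and their test direction lower. Of 15 immune cell markers 0 passed, also when adjusted over the list alone, and the median was -0.13 (camera adjusted p = 0.035, and adjusted p = 0.47 with an estimated correlation). That call was lost without WT_E2 replicate 1 (adjusted p = 0.0675), WT_DMSO replicate 2 (0.126), WP_E2 replicate 2 (0.109) or WP_DMSO replicate 2 (0.129). The limma test called 117 genes, 86 higher and 31 lower. Leaving out a library moved this count to 50 (WT_E2 replicate 1), 52 (WT_E2 replicate 2), 208 (WT_DMSO replicate 1), 77 (WT_DMSO replicate 2) and 60 (WP_DMSO replicate 1). It was 44 with only the WT and WP libraries in the fit, and 0 with WP_E2 replicate 1 counted as DMSO.

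Averaged over both transgenic genotypes, estradiol raised Tmod1 by 1.95 ± 0.19 (n = 4 against 4, adjusted p = 0.00023), Pgr by 1.46 ± 0.10 (adjusted p = 5.7e-06), Greb1 by 1.26 ± 0.14 (adjusted p = 0.00056), Ngfr by 1.22 ± 0.10 and Kdr, a VEGF receptor gene, by 0.71 ± 0.10 (adjusted p = 0.0018). Myog, the muscle transcription factor myogenin, fell (-0.76 ± 0.11, adjusted p = 0.0030), and so did Il6 (-0.58 ± 0.07, adjusted p = 0.00074), Cxcl1 (-0.50 ± 0.06) and Ccl2 (-0.43 ± 0.06). These genes passed also without each library in turn. Of 27 immediate early genes 7 were lower, 0 higher and 20 not passed, with 1 higher and 15 lower when adjusted over the list alone (median -0.13, camera adjusted p = 8.2e-10, and adjusted p = 0.15 with an estimated correlation). Of 27 NF-kB and cytokine genes 5 were lower, 0 higher and 22 not passed, with 3 higher and 7 lower when adjusted over the list alone (median -0.0039, mean -0.10, camera adjusted p = 0.0089, and adjusted p = 0.14 with an estimated correlation). Without single libraries that median was -0.035 (hERa_E2 replicate 1), -0.025 (hERa_E2 replicate 2), -0.017 (hERa_DMSO replicate 1), -0.025 (hERa_DMSO replicate 2), -0.028 (mERa_E2 replicate 1), -0.017 (mERa_E2 replicate 2), -0.030 (mERa_DMSO replicate 1) and -0.057 (mERa_DMSO replicate 2). None of 23 unfolded protein response genes passed, 9 were higher when adjusted over the list alone, and the median was 0.16 (camera adjusted p = 6.1e-11, and adjusted p = 0.34 with an estimated correlation). It was 0.067 without mERa_E2 replicate 2 and 0.27 without mERa_E2 replicate 1. Of cell type markers, 0 of 27 basal and myoepithelial genes passed and 1 was higher when adjusted over the list alone (median 0.076, camera adjusted p = 7.7e-05, and adjusted p = 0.19 with an estimated correlation). Of 14 endothelial markers 2 were higher, also when adjusted over the list alone (median 0.096, camera adjusted p = 0.022, and adjusted p = 0.39 with an estimated correlation). The endothelial call was lost without hERa_E2 replicate 2 (adjusted p = 0.186), hERa_DMSO replicate 1 (median 0.049, adjusted p = 0.0724) or mERa_DMSO replicate 1 (0.053, adjusted p = 0.0555). Its median was 0.058 without mERa_E2 replicate 2 and 0.15 without mERa_DMSO replicate 2. The MCF7 list had 3 higher and 0 lower of 58 and the mouse list 3 higher and 3 lower of 31, neither called (adjusted p = 0.19 and 0.64). When adjusted over the list alone, 6 were higher and 2 lower, and 4 higher and 4 lower. The limma test called 128 genes, 85 higher and 43 lower. The count was 65 without hERa_E2 replicate 1, 59 without hERa_E2 replicate 2, 66 without hERa_DMSO replicate 1, 48 without hERa_DMSO replicate 2, 50 without mERa_E2 replicate 2, 48 without mERa_DMSO replicate 1 and 64 without mERa_DMSO replicate 2. With no mean-variance trend it was 69.

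The response with a transgene was set against the response without one. The 2 mean responses share no library, and 44 genes were called higher in both, where 0.518 would be expected for independent lists, and 8 lower in both, where 0.0944 would be expected. Both tests used the same estimate of each gene's spread, which favors genes with a low estimate in both. The expected numbers may therefore be too low. Of the 193 genes called in either, 151 (78.2%) had the same sign. Ngfr, Pgr, Tmem86a and Myh14 were among the 10 genes called in all 4 genotypes. The response of Greb1 with a transgene minus that without was -1.16 ± 0.20, which did not pass (adjusted p = 0.14), and neither did those of Ptpn5 at -1.21 ± 0.20 (adjusted p = 0.14), Trim30a at -0.38 ± 0.06 (adjusted p = 0.13) and Pgr at -0.36 ± 0.15 (adjusted p = 0.31). The limma test of the difference called 0 genes, with 1939 at an unadjusted p under 0.05 and 0 calls by limma-voom. Without WT_DMSO replicate 1 it called 3 genes, without WP_E2 replicate 1 it called 5, without WP_DMSO replicate 2 it called 1, and without mERa_E2 replicate 1 it called 21. It called 10 without the 3 libraries that stand apart. Greb1 passed without WP_DMSO replicate 2 (-1.36, adjusted p = 0.00401), and Trim30a without WT_DMSO replicate 1 (adjusted p = 0.0195), WP_E2 replicate 1 (0.0304) or mERa_E2 replicate 1 (0.0339). Of 35 interferon-stimulated genes 0 passed, 25 were lower when adjusted over the list alone, and the median was -0.22 (camera adjusted p = 6.2e-20, and adjusted p = 0.062 with an estimated correlation). The response without a transgene in this difference came mostly from WT (median 0.26, against 0.046 in WP), where the label of WT_DMSO replicate 2 does not name the adenovirus. WT_DMSO replicate 1, whose label names it, had a similar list median (9.40, beside 9.35 in replicate 2).

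**Figure D2:**
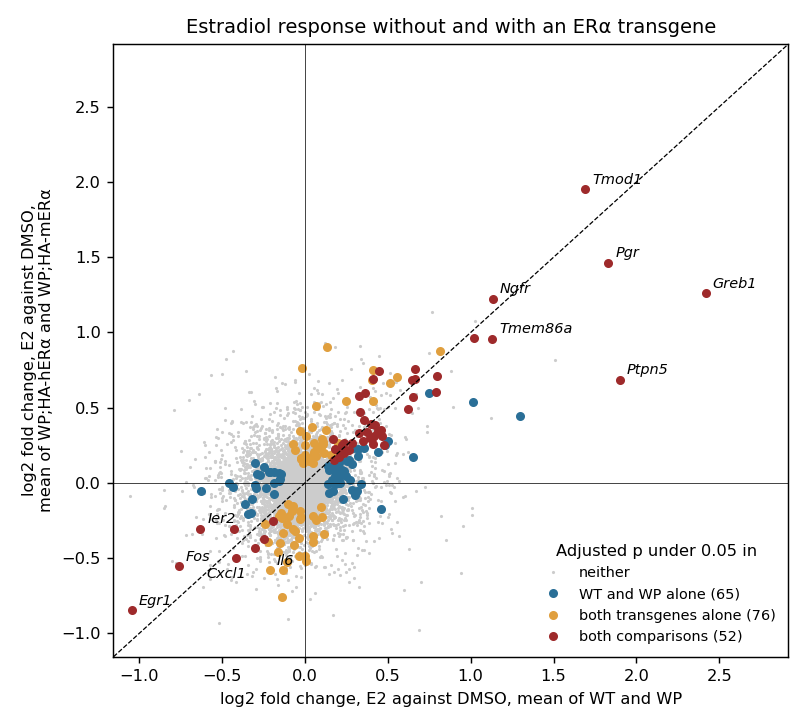
Log2 fold change of each tested gene with E2 against DMSO, averaged over WT and WP (horizontal axis) and over both transgenic genotypes (vertical axis), with a dashed line where both are equal and colors for adjusted p under 0.05. In all, 52 genes passed in both comparisons, and Greb1 lay at 2.42 without and 1.26 with a transgene.

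The human and the mouse receptor were set against each other in the same way. Pgr differed by 0.50 ± 0.21 (hERa minus mERa, adjusted p = 0.72) and Greb1 by 0.58 ± 0.29 (adjusted p = 0.78), and neither passed. The genes with the smallest p were Dennd2a (0.50 ± 0.09) and P4ha1 (0.30 ± 0.06), a subunit of collagen prolyl hydroxylase, both with an adjusted p of 0.40, and both passed without mERa_E2 replicate 1 (adjusted p = 0.0296 and 0.0210). The limma test called 0 genes, with 917 at an unadjusted p under 0.05 and 0 calls by limma-voom. It called 2 genes without hERa_DMSO replicate 1 and 40 without mERa_E2 replicate 1. Of 23 unfolded protein response genes 0 passed, 4 were lower with the human receptor when adjusted over the list alone, and the median was -0.29 (camera adjusted p = 1.4e-12, and adjusted p = 0.29 with an estimated correlation). It was -0.073 without mERa_E2 replicate 2 and -0.47 without mERa_E2 replicate 1. Of 23 fibroblast markers 0 passed, 5 were higher when adjusted over the list alone, and the median was 0.17 (camera adjusted p = 2.4e-06, and adjusted p = 0.17 with an estimated correlation).

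WP cells, with the floxed p53 background, were compared with WT cells over both treatments, 4 libraries against 4. Trp53 fell by 1.60 on the log2 scale (SE 0.07, adjusted p = 3.9e-10), and p53 target genes fell with it: of 56 tested, 45 were lower, 3 higher and 8 not passed, the same when adjusted over the list alone. Among them were the cell cycle inhibitor gene Cdkn1a at -1.49 ± 0.05 (adjusted p = 1.4e-11), Ccng1 at -1.56 ± 0.05, Eda2r at -2.13 ± 0.07 and Mdm2, the gene of the ubiquitin ligase of p53, at -0.98 ± 0.03. The list's median was -0.51 (camera adjusted p = 1.5e-13, and adjusted p = 0.062 with an estimated correlation). Genes of mitosis and S phase rose, 44 of 48 with 0 lower and 4 not passed, and 45 when adjusted over the list alone (median 0.98, camera adjusted p = 1.8e-23, and adjusted p = 0.11 with an estimated correlation), among them the mitotic kinase genes Plk1 (1.24 ± 0.05) and Aurka (1.15 ± 0.05). All 35 interferon-stimulated genes rose, also when adjusted over the list alone, with Oas2 at 3.43 ± 0.10 and Irf7 at 2.32 ± 0.05 (median 1.37, camera adjusted p = 7.1e-25, and adjusted p = 0.062 with an estimated correlation). Of 27 NF-kB and cytokine genes 23 were higher, 2 lower and 2 not passed, the same when adjusted over the list alone (median 0.59, camera adjusted p = 3.1e-07, and adjusted p = 0.056 with an estimated correlation), with Csf2 at 2.26 ± 0.07. Esr1 (-0.47 ± 0.07, adjusted p = 5.1e-05), Pgr (-0.81 ± 0.10, adjusted p = 1.4e-05) and Greb1 (-0.65 ± 0.14, adjusted p = 0.0015) fell, while Areg rose by 0.63 ± 0.09 (adjusted p = 5.5e-05).

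Cell type markers moved with the same contrast. Immune cell markers fell, 14 of 15 with 0 higher and 1 not passed, the same when adjusted over the list alone, with the macrophage genes Lyz2 at -1.60 ± 0.06 and Mrc1 at -1.33 ± 0.10 (median -1.19, camera adjusted p = 3.6e-07, and adjusted p = 0.11 with an estimated correlation). Luminal keratins and junction genes had 16 higher, 1 lower and 1 not passed of 18, the same when adjusted over the list alone, with Krt8 at 0.95 ± 0.04 and Krt18 at 0.99 ± 0.05 (median 0.54, camera adjusted p = 4.7e-08, and adjusted p = 0.11 with an estimated correlation). Basal and myoepithelial markers had 22 lower, 2 higher and 3 not passed of 27, the same when adjusted over the list alone, with Krt5 at -0.97 ± 0.04 (median -0.53, camera adjusted p = 2.2e-08, and adjusted p = 0.10 with an estimated correlation). Fibroblast markers had 16 lower, 2 higher and 5 not passed of 23, the same when adjusted over the list alone, with the collagen gene Col3a1 at -0.95 ± 0.05 (median -0.46, camera adjusted p = 1.6e-05, and adjusted p = 0.19 with an estimated correlation). Luminal progenitor and alveolar markers had 8 higher and 1 lower of 15, the same when adjusted over the list alone, led by the milk protein gene Csn3 at 3.04 ± 0.05 (median 0.32, camera adjusted p = 0.0059, and adjusted p = 0.28 with an estimated correlation).

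The camera test also called 3 further lists. Cholesterol synthesis had 15 lower and 2 higher of 24 (median -0.19, camera adjusted p = 0.0039, and adjusted p = 0.60 with an estimated correlation). Hypoxia and glycolysis had 15 lower and 2 higher of 27 (median -0.16, camera adjusted p = 0.0018, and adjusted p = 0.53 with an estimated correlation). Immediate early genes had 16 higher and 6 lower of 27 (median 0.37, camera adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation), with a median of 0.22 without WT_DMSO replicate 2. When adjusted over the list alone, these counts were the same for cholesterol synthesis, 3 higher and 15 lower for hypoxia, and 17 higher and 6 lower for immediate early genes. The other lists were not called: endothelial markers (7 higher, 2 lower of 14), hormone-sensing luminal markers (9 and 4 of 16), adipocyte markers (1 and 4 of 6), the unfolded protein response (5 and 9 of 23), the MCF7 estrogen list (21 and 16 of 58) and the mouse estrogen list (15 and 10 of 31), with the same counts when adjusted over the list alone except 8 higher endothelial markers. The MCF7 list had a median of -0.01, a mean of 0.07 and a test direction of higher. By limma, 8207 of 14116 genes differed between WP and WT, 4040 higher and 4167 lower, and 614 of them by a factor of 2 or more. The 2 genotypes differ in every allele that the label WP stands for, and the labels give no batch. They may also differ in exposure to the Cre adenovirus, which the WP titles name and the WT titles do not.

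WP;HA-hERa cells were compared with WP cells, which lack the human receptor transgene. Trp53 and cell type markers differed as well, and the labels give no batch, so the changes cannot be assigned to the receptor alone. Pgr rose by 0.84 ± 0.10 (n = 4 against 4, adjusted p = 1.9e-05) and Greb1 by 0.92 ± 0.14 (adjusted p = 0.00016). With E2 libraries only, Greb1 did not pass at 0.38 ± 0.20 (n = 2 against 2, adjusted p = 0.21). WP lay below WT in both genes. Mean levels of Pgr with E2 and in DMSO were 7.80 and 6.09 in WP;HA-hERa, against 7.88 and 5.96 in WT, which has no transgene. Those of Greb1 were 7.56 and 6.00 against 7.62 and 5.40. Areg did not pass at -0.23 ± 0.09 (adjusted p = 0.068), and mouse Esr1 (-0.40 ± 0.07, adjusted p = 0.00037) and Trp53 (-0.86 ± 0.07, adjusted p = 3.5e-07) fell. Areg passed without WP_E2 replicate 2 (adjusted p = 0.0261). The genes with the largest decreases were the cardiac actin gene Actc1 at -3.30 ± 0.12, the ATP-gated channel gene P2rx1 at -3.25 ± 0.39, the embryonic myosin gene Myh3 at -3.07 ± 0.14 and the acetylcholine receptor gene Chrng at -2.97 ± 0.23. Fibroblast markers fell, 21 of 23 with 0 higher and 2 not passed, and 1 higher and 21 lower when adjusted over the list alone, with Lum at -1.81 ± 0.06 and Dcn at -1.50 ± 0.05 (median -0.90, camera adjusted p = 8.0e-17, and adjusted p = 0.062 with an estimated correlation). Endothelial markers had 12 lower and 0 higher of 14, the same when adjusted over the list alone, with Cdh5 at -1.24 ± 0.09 (median -0.77, camera adjusted p = 1.6e-06, and adjusted p = 0.099 with an estimated correlation). Members of the luminal keratin list and of the luminal progenitor list were mostly higher: 16 of 18 luminal keratins and junction genes (18 when adjusted over the list alone, median 0.31, camera adjusted p = 3.7e-09, and adjusted p = 0.10 with an estimated correlation) and 12 of 15 luminal progenitor and alveolar markers, with 1 lower (the same when adjusted over the list alone, median 0.44, camera adjusted p = 2.2e-05, and adjusted p = 0.11 with an estimated correlation). The alveolar transcription factor gene Elf5 rose by 1.45 ± 0.10 and the milk protein gene Wfdc18 by 1.60 ± 0.10. Hormone-sensing luminal markers showed no such rise. Their mean log2 level per library was 7.33 to 7.63 in WP and 7.34 to 7.56 in WP;HA-hERa. Basal and myoepithelial markers went both ways, with 13 higher and 6 lower of 27, the same when adjusted over the list alone (median 0.27, camera adjusted p = 0.017, and adjusted p = 0.46 with an estimated correlation). Krt5, a basal keratin, rose by 1.08 ± 0.04.

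Cholesterol synthesis genes also fell in WP;HA-hERa, 21 of 24 with 0 higher, the same when adjusted over the list alone (median -0.32, camera adjusted p = 1.5e-08, and adjusted p = 0.35 with an estimated correlation). NF-kB and cytokine genes had 5 higher and 11 lower of 27, and 5 and 12 when adjusted over the list alone (median -0.15, camera adjusted p = 0.029, and adjusted p = 0.19 with an estimated correlation). Cxcl5 was at -2.60 ± 0.11, Ccl2 at -1.60 ± 0.06 and the adhesion gene Icam1 at 0.85 ± 0.05. Genes of mitosis and S phase had 27 higher and 2 lower of 48, and 31 and 2 when adjusted over the list alone (median 0.18, camera adjusted p = 1.6e-06, and adjusted p = 0.46 with an estimated correlation). Of the 3 libraries low in AT-rich transcripts, 2 were WP and 1 was WP;HA-hERa, and Mki67 did not pass at 0.24 ± 0.28 (adjusted p = 0.52). Neither estrogen list was called: 19 of 58 MCF7 genes were higher and 11 lower (adjusted p = 0.37), and 12 of 31 mouse genes higher and 11 lower (adjusted p = 0.88). When adjusted over the list alone, the MCF7 counts were the same and the mouse list had 14 higher and 12 lower. The mouse list had a median of 0.08, a mean of -0.02 and a test direction of higher. By limma, 5492 genes differed, 2627 higher and 2865 lower. With E2 libraries only, 3294 were called.

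WP;HA-mERa cells were compared with WP cells, which lack the mouse receptor transgene. Here too cell type markers differed and the labels give no batch, so the changes cannot be assigned to the receptor alone. Esr1 rose by 1.90 ± 0.07 (n = 4 against 4, adjusted p = 1.0e-09), Pgr by 2.15 ± 0.10 (adjusted p = 9.5e-09), Greb1 by 2.23 ± 0.14 (adjusted p = 1.2e-07) and Tmod1 by 2.78 ± 0.19. Trp53 did not pass at -0.13 ± 0.07 (adjusted p = 0.14) and passed without WP_DMSO replicate 2 (-0.23, adjusted p = 0.00417). Areg did not pass at 0.16 ± 0.09 (adjusted p = 0.17) and passed without mERa_E2 replicate 1 (adjusted p = 0.0478). In DMSO alone, without added hormone, Greb1 was higher by 3.05 ± 0.20 (n = 2 against 2, adjusted p = 7.4e-07), Pgr by 2.42 ± 0.15 (adjusted p = 3.0e-07) and Ptpn5 by 2.34 ± 0.20 (adjusted p = 6.7e-06). The same contrast for WP;HA-hERa gave 1.45 ± 0.20 for Greb1, 0.85 ± 0.15 for Pgr, and for Ptpn5 0.43 ± 0.20, which did not pass (adjusted p = 0.13). Neither estrogen list was called in WP;HA-mERa: 15 of 58 MCF7 genes were higher and 14 lower (adjusted p = 0.34), and 11 of 31 mouse genes higher and 10 lower (adjusted p = 0.51), with 15 and 14 and 12 and 10 when adjusted over the list alone. Stc2, an estrogen-induced secreted glycoprotein of MCF7 cells, rose by 0.88 ± 0.05 and Aqp5, a water channel, by 1.60 ± 0.06, while the cyclin gene Ccnd1 fell (-0.47 ± 0.04).

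Genes of mitosis and S phase fell in WP;HA-mERa, 41 of 48 with 0 higher and 7 not passed, the same when adjusted over the list alone (median -0.44, camera adjusted p = 6.1e-17, and adjusted p = 0.17 with an estimated correlation), with Rrm2 at -0.73 ± 0.06 and Plk1 at -0.59 ± 0.05. Immune cell markers rose beside them, 12 of 15 with 0 lower, the same when adjusted over the list alone (median 1.11, camera adjusted p = 1.2e-08, and adjusted p = 0.080 with an estimated correlation), with Lyz2 at 1.25 ± 0.06 and Mrc1 at 1.34 ± 0.10. Luminal keratins and junction genes had 15 lower and 0 higher of 18, the same when adjusted over the list alone (median -0.30, camera adjusted p = 1.1e-07, and adjusted p = 0.11 with an estimated correlation), with Krt7 at -0.70 ± 0.04. Basal and myoepithelial markers had 15 higher and 5 lower of 27, and 17 and 5 when adjusted over the list alone (median 0.17, camera adjusted p = 0.0058, and adjusted p = 0.39 with an estimated correlation). Luminal progenitor and alveolar markers had 1 higher and 8 lower of 15, the same when adjusted over the list alone (median -0.20, camera adjusted p = 0.030, and adjusted p = 0.40 with an estimated correlation), a call lost with GC correction (adjusted p = 0.0706). Endothelial markers had 10 lower and 1 higher of 14, the same when adjusted over the list alone (median -0.86, camera adjusted p = 0.0047, and adjusted p = 0.27 with an estimated correlation). The unfolded protein response had 15 higher and 0 lower of 23, the same when adjusted over the list alone (median 0.28, camera adjusted p = 3.6e-07, and adjusted p = 0.46 with an estimated correlation), with Trib3 at 0.95 ± 0.04 and Ppp1r15a at 1.17 ± 0.07, and its median was 0.46 without mERa_E2 replicate 1. Cholesterol synthesis had 20 lower and 0 higher of 24, and 21 lower when adjusted over the list alone (median -0.28, camera adjusted p = 1.2e-09, and adjusted p = 0.31 with an estimated correlation), with Hmgcs1 at -0.67 ± 0.05. By limma, 6647 genes differed, 3310 higher and 3337 lower. With DMSO libraries only, 4352 were called.

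Both transgenic genotypes were compared with the same WP libraries, so their changes share chance values. Their log2 fold changes had a Pearson correlation across genes of 0.134 and a Spearman correlation of 0.0449, while simulated unchanged groups against the same controls gave 0.499 and 0.451. The covariance was 0.0166 against 0.00664 in the simulation, a difference of 0.010. With the WP libraries split between the comparisons, the Pearson correlation was 0.0699 and 0.00522. In both comparisons 558 genes were called higher, where 616 would be expected for independent lists, and 717 lower, where 677 would be expected, and 1679 genes were called in opposite directions. The simulation gave 0.06 genes called in both in either direction. Genes are not independent replicates.

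**Figure D3:**
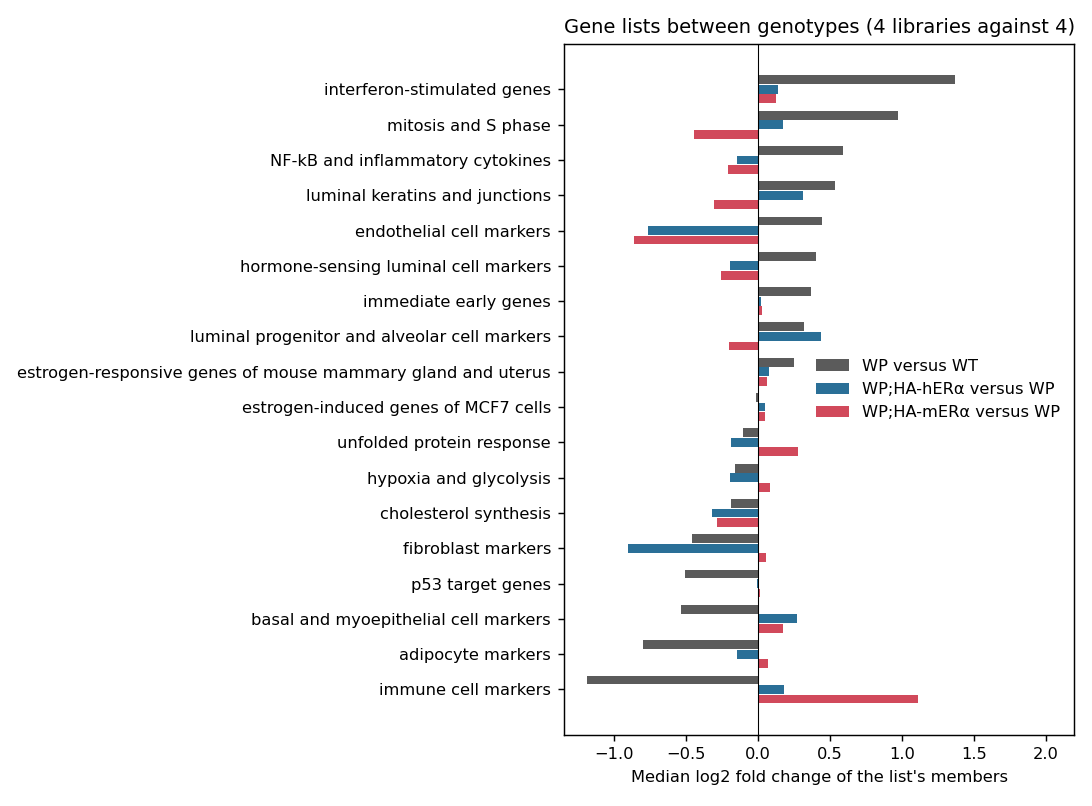
Median log2 fold change of the tested members of each gene list, over both treatments, for WP against WT, WP;HA-hERa against WP and WP;HA-mERa against WP, with a bar per comparison and 4 libraries against 4. Interferon-stimulated genes stood at 1.37 in WP against WT, fibroblast markers at -0.90 in WP;HA-hERa and immune cell markers at 1.11 in WP;HA-mERa.

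Set directly against WP;HA-mERa, WP;HA-hERa cells had less mouse Esr1 (-2.30 ± 0.07, n = 4 against 4, adjusted p = 1.6e-11), Pgr (-1.32 ± 0.10, adjusted p = 9.9e-08), Greb1 (-1.31 ± 0.14, adjusted p = 3.1e-06), Areg (-0.39 ± 0.09, adjusted p = 0.0027) and Trp53 (-0.73 ± 0.07, adjusted p = 8.2e-07). The carbonic anhydrase gene Car2 was higher by 3.03 ± 0.07, Txnip, an inhibitor of thioredoxin, by 2.87 ± 0.13, and the milk protein gene Ltf by 2.84 ± 0.24. All 18 luminal keratins and junction genes were higher, also when adjusted over the list alone (median 0.65, camera adjusted p = 3.7e-11, and adjusted p = 0.075 with an estimated correlation). Luminal progenitor and alveolar markers had 13 higher and 1 lower of 15, and 13 and 2 when adjusted over the list alone (median 0.56, camera adjusted p = 2.3e-05, and adjusted p = 0.11 with an estimated correlation). Genes of mitosis and S phase had 44 higher and 0 lower of 48, the same when adjusted over the list alone (median 0.61, camera adjusted p = 6.1e-17, and adjusted p = 0.17 with an estimated correlation). Fibroblast markers had 22 lower and 0 higher of 23, the same when adjusted over the list alone (median -0.90, camera adjusted p = 2.6e-12, and adjusted p = 0.075 with an estimated correlation), and immune cell markers 14 lower and 0 higher of 15, the same when adjusted over the list alone (median -0.84, camera adjusted p = 2.1e-05, and adjusted p = 0.15 with an estimated correlation). The unfolded protein response had 22 lower and 0 higher of 23, the same when adjusted over the list alone (median -0.47, camera adjusted p = 3.1e-08, and adjusted p = 0.41 with an estimated correlation), with Chac1 at -1.14 ± 0.04. By limma, 8167 genes differed, 4023 higher and 4144 lower. Over all comparisons camera called 89 list results, of which only a part is described, and no camera call of any comparison held with an estimated correlation. With fry, 59 of the 89 held in the same direction.

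MCF7 cells served as a human line with high ERα and were measured in full medium only. ESR1 had a log2 level of 12.41 ± 0.01 (SD, n = 2), with 5943 and 5376 reads, at the 97.6th percentile of the 12273 genes above the filter. In MMECs, mouse Esr1 lay at percentiles of 31.9 (WT_E2), 31.4 (WT_DMSO), 28 (WP_E2), 27.1 (WP_DMSO), 24.3 (hERa_E2), 24.6 (hERa_DMSO), 50.4 (mERa_E2) and 50.7 (mERa_DMSO) of their own table. The 2 tables were normalised separately, so only ranks within each are set side by side and no test was made. The luminal transcription factor gene GATA3 was at 13.30, the estrogen-induced genes GREB1 at 12.30 ± 0.03, TFF1 at 13.08 and PGR at 9.55 ± 0.10, and AREG at 6.23 ± 0.28. KRT8 was at 16.11, while the basal keratin gene KRT5 had 0 and 2 reads. The 63 MCF7 estrogen genes had a median level of 9.61, and the 33 estrogen genes of mouse tissues, 22 of them above the filter, a median of 6.22.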

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

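No group had 4 or more samples, so a search for a library far from its group could not be made. The tests of immune cells in the WP cultures and of fibroblasts in the WP;HA-hERa cultures were chosen after the results were seen, and so were all tests that corrected for GC content. Each SE of a median is over the genes of its list, not over libraries.

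For 10 gene lists the response to estradiol differed between groups by the camera test, although 0 single genes did, and none held when the correlation between genes was estimated. With a transgene minus without, the median difference in log2 response was 0.12 for basal and myoepithelial markers (adjusted p = 0.00032, and adjusted p = 0.25 with an estimated correlation). It was -0.086 for cholesterol synthesis (adjusted p = 0.00041, and adjusted p = 0.54 with an estimated correlation) and -0.22 for interferon-stimulated genes (adjusted p = 6.2e-20, and adjusted p = 0.062 with an estimated correlation). It was -0.077 for mitosis and S phase (adjusted p = 0.00047, and adjusted p = 0.58 with an estimated correlation), which was lost without WT_DMSO replicate 1 (adjusted p = 0.115), and 0.14 for the unfolded protein response (adjusted p = 1.6e-06, and adjusted p = 0.49 with an estimated correlation). Single libraries moved these medians: without mERa_E2 replicate 2 the unfolded protein response was at 0.052 and cholesterol synthesis at -0.050, without mERa_E2 replicate 1 the unfolded protein response was at 0.24, and without WT_DMSO replicate 2 mitosis was at -0.13.

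With the human receptor minus the mouse receptor, the median difference was 0.11 for cholesterol synthesis (adjusted p = 2.7e-05, and adjusted p = 0.49 with an estimated correlation), 0.17 for fibroblast markers (adjusted p = 2.4e-06, and adjusted p = 0.17 with an estimated correlation) and 0.13 for hypoxia and glycolysis (adjusted p = 0.0012, and adjusted p = 0.52 with an estimated correlation). It was -0.12 for NF-kB and cytokine genes (adjusted p = 0.013, and adjusted p = 0.16 with an estimated correlation) and -0.29 for the unfolded protein response (adjusted p = 1.4e-12, and adjusted p = 0.29 with an estimated correlation). Without mERa_E2 replicate 2, cholesterol synthesis (median 0.033, adjusted p = 0.366) and hypoxia (0.024, adjusted p = 0.487) were lost, and the median of the unfolded protein response was -0.073. Without mERa_E2 replicate 1 these medians were 0.20, 0.20 and -0.47. The NF-kB list was lost without hERa_E2 replicate 2 (median -0.050, adjusted p = 0.0862) or mERa_E2 replicate 1 (adjusted p = 0.0971), and its median was -0.072 without hERa_DMSO replicate 2 and -0.078 without mERa_DMSO replicate 1.

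Interferon-stimulated genes were higher in WP than in WT by a median of 1.37 (SE 0.13). WT_DMSO replicate 2, whose label omits the Cre adenovirus, lay -0.23 (SE 0.03) from the other 3 WT libraries. If the treatment labels are right, that is too little to account for the difference. However, no WT title names AdCre, and if no WT culture received the virus, this test cannot decide. From the WT_E2 libraries, WT_DMSO replicate 1, whose label names the virus, lay -0.22 (SE 0.03) and replicate 2 lay -0.30 (SE 0.02). The immune cell markers moved by -1.19 (SE 0.08), which argues against more immune cells in the WP cultures, and after GC correction the median was 1.38 (SE 0.12), which argues against GC content. A difference in virus exposure, virus dose or culture date between genotypes could not be tested.

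Fibroblast markers were lower in WP;HA-hERa than in WP by a median of -0.90 (SE 0.11), with single genes from -1.81 to 0.16. Of the luminal keratin and basal markers that were called, 82.9% (29, against 6 lower) were higher, as a smaller share of fibroblasts in the cultures would give, so that explanation stays open. After GC correction the median was -0.91 (SE 0.12), which argues against GC content. Bulk RNA cannot tell fewer fibroblasts from less expression per cell.

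Genes induced by estradiol were higher in vehicle-treated WP;HA-mERa than in vehicle-treated WP cells. The 38 genes chosen in WT alone, which share no library with this contrast, had a median of 0.29 (SE 0.05), so the choice of genes in the control libraries does not explain it. That median lay at percentile 100 of 10000 random lists of like expression, whose highest median was 0.19, and after GC correction it was 0.289 (SE 0.06). For WP;HA-hERa the same 38 genes had a median of 0.097 (SE 0.05), at percentile 98.25 of such random lists. A higher level of receptor with residual hormone in the medium and a receptor active without hormone would both give the WP;HA-mERa result and were not told apart. Cell type markers also differed between WP;HA-mERa and WP, so causes other than the receptor stay open.

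Where the libraries could be divided anew, genotype or treatment was kept as a term. In each of 6 comparisons, 1 of 34 divisions gave as many called genes as the real one, that one being the real one. In the genotype comparisons every other division mixed both genotypes, and for estradiol every other division mixed E2 with DMSO libraries. That puts the difference into the spread and keeps the count low. Some of the other divisions also held unequal shares of the genotypes or treatments kept as a term, unlike the real one. The count therefore cannot decide about chance in these comparisons. Chance differences between cultures or animals are not excluded in any comparison, because the labels do not say whether replicates were separate ones. The real count and the highest other were 115 and 1 for estradiol with a transgene, 50 and 3 without, 7723 and 0 for WP against WT, 4929 and 0 for WP;HA-hERa against WP, 5944 and 1 for WP;HA-mERa against WP, and 8396 and 0 for WP;HA-hERa against WP;HA-mERa. For the difference in response with and without a transgene, the real count was 0 and the highest other 0, so all 35 of 35 divisions gave as many by construction and the count says nothing about chance. For the human against the mouse receptor there were only 3 divisions, all with as many (real 0, highest other 0), too few for a share under 0.05.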

How the results depend on the processing

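With 2 libraries per group, the calls for estradiol within a genotype depended on single libraries, while the counts of the genotype comparisons stayed within 1.5 times without any library. No called value of a named gene changed sign under any setting. In a group with a library left out, the remaining library was assumed to vary like the other groups. All 12 counts stayed within 1.5 times with limma-voom, a pseudocount of 8, quantile normalization, the stricter filter and GC correction. Where a count moved, the cause was not tested. Settings added after the data were seen were GC correction (also with a replicate block), leaving out the 3 libraries that stand apart, and the list tests without each library, without those 3 and with GC correction. Of 469 called values of named genes, 16 were lost with limma-voom, 19 with GC correction, 42 with no filter, 51 with only the groups compared and 54 with no mean-variance trend. Of values not called, 3 of 44 changed sign without the 3 libraries, 1 of 20 with WP_E2 replicate 1 counted as DMSO, and at most 4 (of 29, without hERa_DMSO replicate 1) with a single library left out. Of 89 list calls, 62 held without every library, 84 with GC correction and 88 without the 3 libraries, and 85 with quantile normalization. Lists not called at first were called in the opposite direction in 2 cases without mERa_E2 replicate 2 and in 1 without WT_DMSO replicate 1.

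With no filter, 33 genes were called for estradiol in WP;HA-hERa and 14 in WP;HA-mERa. With no mean-variance trend these were 26 and 10, and 69 for the mean of the transgenes. With only the groups compared in the fit, 69 were called in WT, 0 in WP, 19 in WP;HA-hERa and 44 for the mean of WT and WP. With WP_E2 replicate 1 counted as DMSO, 8 were called in WP and 0 for the mean of WT and WP. With DMSO libraries only, WP;HA-mERa against WP gave 4352, and with E2 libraries only, WP;HA-hERa against WP gave 3294. Without the 3 libraries that stand apart, 147 were called in WT, 139 in WP;HA-mERa and 10 for the response with minus without a transgene. ESR1 in MCF7 lay at percentile 98.5 among all genes listed.

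Lowest and highest counts with a library left out were 15 (WT_E2 replicate 1) and 38 (WT_DMSO replicate 1) for estradiol in WT, 10 (WP_DMSO replicate 1) and 117 (WP_E2 replicate 2) in WP, 10 (hERa_DMSO replicate 2) and 29 (hERa_DMSO replicate 1) in WP;HA-hERa, and 2 (mERa_E2 replicate 2) and 175 (mERa_E2 replicate 1) in WP;HA-mERa. They were 50 (WT_E2 replicate 1) and 208 (WT_DMSO replicate 1) for the mean of WT and WP and 48 (hERa_DMSO replicate 2) and 187 (mERa_E2 replicate 1) for the mean of the transgenes. They were 0 (WT_E2 replicate 1) and 21 (mERa_E2 replicate 1) for the response with minus without a transgene, and 0 (hERa_E2 replicate 1) and 40 (mERa_E2 replicate 1) for the human minus the mouse receptor.

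The labels do not say that replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.0209 in WT, 0.211 in WP, -0.0294 in WP;HA-hERa and 0.0978 in WP;HA-mERa. Of all 28 pairs of groups, 3 were over 0.1: WP_E2 with hERa_E2 at 0.305, WP_DMSO with hERa_E2 at 0.220 and WP_E2 with WP_DMSO at 0.211. These are the groups of the 3 libraries that stand apart. The other 25 were not over 0.1, so the numbers were not taken to pair the libraries in general. With a replicate block over all libraries the counts were 61, 21, 53 and 54 in WT, WP, WP;HA-hERa and WP;HA-mERa, 131 and 129 for the means of the transgenes and of WT and WP, 0 and 0 for the differences in response, 8320 for WP against WT, 5592 and 6780 for the human and mouse receptor against WP, and 8294 between them. With a replicate block within each genotype, 75 were called in WT, 32 in WP, 100 in WP;HA-mERa, 6 for the response with minus without a transgene and 1 for the human minus the mouse receptor.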

Other observations

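The muscle genes Myog and Des fell in both transgenic genotypes relative to WP; no list of muscle genes was tested. Myog, which drives muscle differentiation, was at -2.66 ± 0.11 (n = 4 against 4, adjusted p = 4.83e-10) in WP;HA-hERa and at -0.72 ± 0.11 (adjusted p = 0.00015) in WP;HA-mERa, and Des, the muscle intermediate filament gene, at -1.67 ± 0.08 and -0.64 ± 0.08. The library levels of Myog were 6.88 to 7.24 in WP, 3.99 to 4.85 in WP;HA-hERa and 5.80 to 6.94 in WP;HA-mERa. With estradiol, Myog fell further as the mean of both transgenic genotypes (-0.76 ± 0.11, adjusted p = 0.0030).

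The 86 genes called higher with estradiol as the mean of WT and WP had median responses of 0.36 in WT, 0.29 in WP, 0.26 in WP;HA-hERa and 0.20 in WP;HA-mERa. In DMSO, 77 of the 86 were higher in WP;HA-mERa than in WP, with a median of 0.26, and 45 were higher in WP;HA-hERa, with a median of 0.060. In WT, which has no transgene, 55 were higher than in WP, with a median of 0.13. Vehicle-treated WP;HA-mERa cells had more Pgr than estradiol-treated WP cells (0.68 ± 0.15, n = 2 against 2, adjusted p = 0.0049) and more Tmod1 (1.03 ± 0.27, adjusted p = 0.015), while Greb1 did not pass (0.43 ± 0.20, adjusted p = 0.14). Other estradiol-induced genes were lower in the same contrast: Btbd3 (-0.34 ± 0.07, adjusted p = 0.0024), Shpk (-0.31 ± 0.11, adjusted p = 0.043) and Tmem86a (-0.19 ± 0.06, adjusted p = 0.036). Ngfr, Msx2, Ctns, Myh14 and Mmp19 were lower and Ptpn5 higher without passing. The WP_DMSO libraries helped to choose the 86 genes, which by itself favors a higher value in the transgenic genotypes. Choosing these genes by their response in WT and WP also favors larger responses there than in the transgenic genotypes.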
